A study of Drosophila melanogaster with 6 samples.

How the data were processed

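Total RNA from ovaries was purified with a Qiagen kit, labelled with biotin by terminal labelling of double-stranded DNA and hybridized to Affymetrix tiling arrays, 3 for uap56 and 3 for vasa. The flies had cornmeal food and wet yeast paste, and the ovaries were dissected in Robb's medium. Per the labels, the deposited values are intensity summarised and normalized by the authors, 1 table per array for RefSeq transcripts and 1 for transposon families named as in FlyBase. The normalization, the choice of probes, the genome build and the alleles are not given in the sources used here. The values are linear. Log2 of each value was taken with no pseudocount, since no value lay between 0 and 1 and the 393 transcripts at 0 on every array were left out, which kept 20765 of 21158 entries. Between 37.5 and 67.5% of an array's transposon values also occurred, to 5 significant digits, in the RefSeq table of the same array, against 1.67 to 12.5% in those of other arrays, and the tables of an array were therefore taken to share a scale. For arrays no depth applies.

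Transcripts were paired with genes through a table of RefSeq accessions and symbols on Release 6 of the fly genome, which was used only for names, chromosome arms and gene order. Of the 21158 entries, 19234 matched by accession, 1341 by the gene name in the file and 583 kept the name in the file, and 444 entries repeated an accession. The transcript with the highest mean stood for its gene, giving 13666 genes. This matching was revised after results had been seen. The matching used before kept older gene models apart from the current gene and listed some genes more than once (14107 entries, 2 past the threshold in the planned fit and 528 in the trend fit). A later correction separated 4 transcripts and 1 list name that had been joined to another gene by letters that differ in case alone. Before it, 2 and 522 of 13664 genes passed in the planned and the trend fit.

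Groups were compared as uap56 minus vasa with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05, separately for 120 transposon families and 13666 genes. The labels give no pairing of the replicate numbers, and the deviations of same-numbered arrays from their group means were not alike, so no block was fitted. This planned fit was set before the data were examined, as were the gene lists, the set tests, the alternatives other than those named below and the rule for named genes. A fit with an intensity trend and robust hyperparameters was among the alternatives, and its use to name genes was decided after the planned fit had given 2 genes. Both fits were tested on simulated data with the spread of these arrays, and changes were placed only in entries above the median intensity. The simulated spread followed intensity, which the trend fit models and the planned fit does not, and entries were drawn independently. The comparison of the fits therefore favours the trend fit, and the false calls do not cover correlated entries. Recovery among dimmer entries was not tested. For such brighter genes the planned fit found 0% of log2 changes of 1 and 73.0% of changes of 2. The trend fit found 48.0% and 94.0%, and false calls over all genes were 5 in the planned and 6 in the trend fit. For transposons the planned fit found 80.0% and 100%, with 0 false calls.

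The genes named are Hel25E, vas and the genes that share the vas locus, vig and solo; the 12 largest differences each way among genes past the threshold with arrays that do not overlap and a mean above the median gene in the higher group; and up to 4 members of each list with the smallest p in the planned fit. Transposons named are the 10 largest differences each way on the same terms and a fixed set of families. Genes named outside this rule are marked in the text, and not every gene that the rule picks is given. Sets were tested with camera at a preset correlation of 0.01, camera with an estimated correlation and fry, over 25 gene lists (640 of 646 names matched) and 6 transposon lists. The gene lists cover the piRNA pathway, mRNA export, germ plasm, early germline, meiosis, chorion, vitelline membrane, yolk, follicle cells, endocycle and DNA replication, DNA damage, heat shock, antimicrobial peptides, detoxification, spliceosome, ribosome, proteasome, oxidative phosphorylation and 7 other cell types. Arms were compared with Fisher's exact test.

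The alternatives were quantile normalization, centring on the array median, the replicate number as a block, leaving out each array, entries above the 25th percentile, a threshold of 0.01, a minimum of 1.5-fold, the intensity trend, a variance per gene alone, transposons fitted with genes, the mean over transcripts and every transcript on its own. A pseudocount of 16, the older gene models kept apart, names joined regardless of letter case, the trend and the robust option each alone, and the trend fit for the arms, for list members and for Hel25E and vas were added after the data had been seen. Matched lists were drawn at random 10000 times among the 50 genes nearest in mean intensity to each family, and bootstrap intervals cover 95% over 10000 draws. Tables were read with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with matplotlib 3.10.9.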

Results

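RNA from Drosophila melanogaster ovaries was measured on 6 Affymetrix tiling arrays, 3 labelled uap56 and 3 labelled vasa. UAP56, encoded by Hel25E, is a DEAD-box helicase of mRNA processing and export, and Vasa, encoded by vas, is a DEAD-box helicase of the germline. The tables gave an intensity for 21158 RefSeq transcript entries and for 120 transposon families on each array. The median transcript intensity lay between 163 and 184 on the 6 arrays, and between 166 and 223 transcripts per array stood at the floor of 1. Across transcripts, Pearson's r between arrays was 0.898 to 0.922 within a group and 0.888 to 0.904 between groups. Across transposon families it was 0.978 to 0.983 within a group and 0.739 to 0.795 between groups. Transcripts and families are not independent replicates. Intensities are given below as means ± SD over the 3 arrays of a group, and log2 differences as uap56 minus vasa. The number of arrays limits the precision. The labels do not say whether the replicates came from separate animals, so the p-values measure the spread between these samples only, which may be technical. Ovaries of flies with both genes intact were not analysed here, so each difference sets uap56 against vasa and does not tell in which group a level moved.

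The groups are named for Hel25E and vas, and the values of both genes were compared as a check of the labels. The vas signal was 5.75-fold higher in uap56, with 1698 ± 341 in uap56 and 297.3 ± 75.1 in vasa (n = 3 each), and the arrays of the groups did not overlap. The log2 difference was 2.52 ± 0.22 (SE), with an adjusted p of 0.00174 in the limma fit with an intensity trend and 0.0894 in the planned limma fit. Over all alternatives the adjusted p of vas ran from 0.00174 to 0.406. Hel25E stood at 1419 ± 326 in uap56 and 1610.3 ± 192 in vasa, a log2 difference of -0.20 with overlapping arrays and an adjusted p of 0.723. Without uap56 replicate 3 the Hel25E difference was 0.00399, with the sign changed. The genes that share the vas locus were not past the threshold. The difference was 0.67 for solo (adjusted p = 0.373) and 0.02 for vig (adjusted p = 0.975), and that of vig changed sign, to -0.02, after quantile normalization.

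The title of the series ties UAP56 to piRNA clusters and to transposon silencing, and the transposon tables show which families differed between the groups. Most families that differed were higher in vasa. The LTR element 3S18 stood at 141 ± 23.9 in uap56 and 7818 ± 779 in vasa (n = 3 each), a 55.9-fold difference. Burdock was higher in vasa by a log2 difference of -4.70 (59.3 ± 7.42 in uap56 and 1536 ± 97.7 in vasa), blood 11.2-fold (458 ± 87.4 in uap56 and 5103 ± 707 in vasa) and diver 7.35-fold (1482 ± 104 in uap56 and 10917 ± 1076 in vasa). In the opposite direction, copia was 13.4-fold higher in uap56, with 13019 ± 2124 in uap56 and 975 ± 159 in vasa. Tirant stood at 62.1 ± 14.8 in uap56 and at or next to the floor in vasa, with 1.00, 1.00 and 1.82 on its arrays, so no fold is given.

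In the planned limma fit, 69 of 120 families passed an adjusted p of 0.05, 62 of them higher in vasa and 7 higher in uap56. A difference of at least 2-fold was found in 40 of the former and 7 of the latter, and one of at least 4-fold in 16 and 2. The arrays of the groups did not overlap for 80 families (66.7%), where chance gives 10%. Besides 3S18, large differences toward vasa were those of Burdock (-4.70, adjusted p = 6.28e-08), blood (-3.49, adjusted p = 8.47e-07), flea (-3.15), Transpac (-2.96) and diver (-2.88), and the family 1731's difference (-2.94) was of like size. The families invader3 (5.56 ± 1.29 in uap56 and 145 ± 27.6 in vasa), BS (16.6 ± 4.29 in uap56 and 144 ± 10.2 in vasa) and accord (12.1 ± 5.999 in uap56 and 87.7 ± 27.5 in vasa) were also among the largest, but lay near the bottom of the scale in uap56, and the size of their differences depends on the treatment of weak signals, with -2.89, -2.30 and -1.88 after a pseudocount of 16 against -4.72, -3.15 and -2.98 without it. The smaller differences toward vasa included jockey (-2.45), the telomeric element TART (-2.16, 47.2 ± 10.9 in uap56 and 225 ± 114 in vasa), I-element (-0.94, adjusted p = 0.00842) and mdg1 (-0.74), and the family 412's difference was -1.10. ZAM, near the bottom of the scale in both groups (6.01 ± 1.14 in uap56 and 9.54 ± 1.14 in vasa), had -0.68 (adjusted p = 0.0180) and -0.22 with a pseudocount of 16. Toward uap56, copia (3.74, adjusted p = 5.87e-07) and Tirant were followed by hobo (1.53), R2-element (1.16, adjusted p = 0.0148) and Bari1 (1.07). Helitron and Stalker3 (1.22) complete the 7, and they were named after their values were seen, since their arrays overlap. Helitron was near the bottom of the scale in both groups (11.5 ± 5.37 in uap56 and 3.91 ± 2.65 in vasa), and its difference was 1.78, or 0.45 with the pseudocount. The call of R2-element was lost without uap56 replicate 2 (adjusted p = 0.0585) or uap56 replicate 3 (adjusted p = 0.0633), and that of ZAM without uap56 replicate 3 (adjusted p = 0.0544), without vasa replicate 1 (adjusted p = 0.0638) and with a pseudocount of 16 (adjusted p = 0.102). Fitted in the same table as the genes, 13 families passed.

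**Figure D1:**
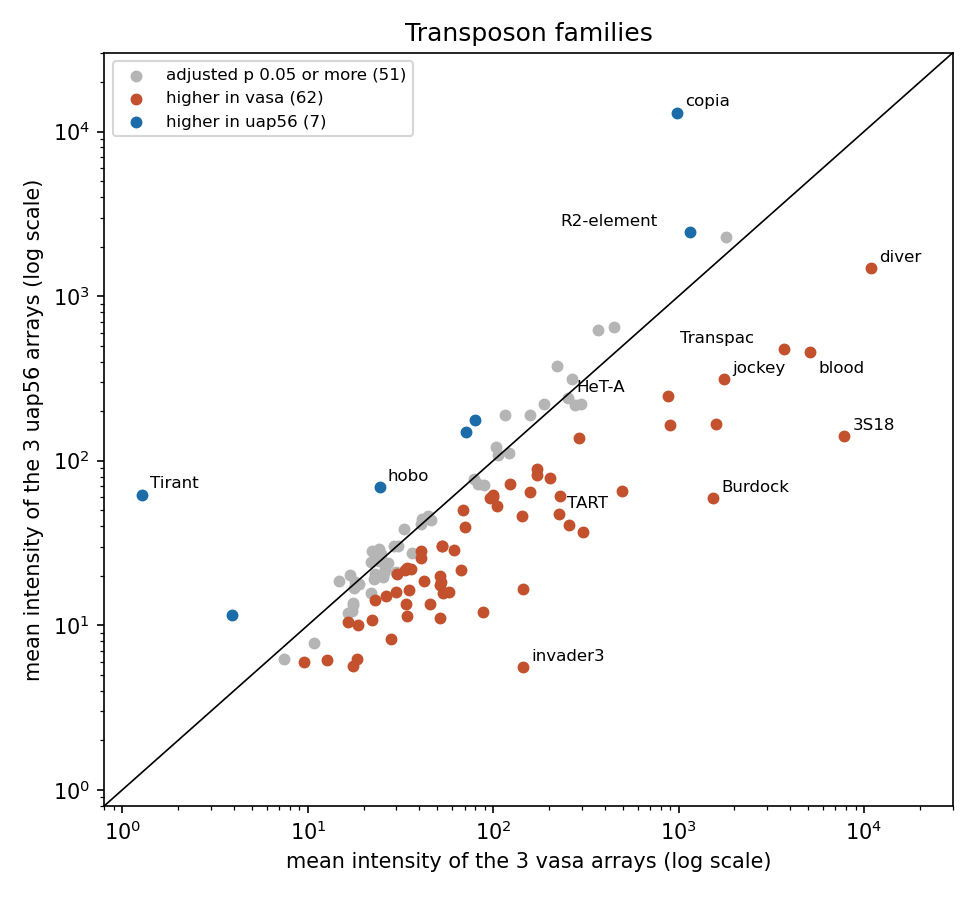
Mean intensity of each of the 120 transposon families in the 3 vasa arrays (horizontal, log scale) and the 3 uap56 arrays (vertical, log scale), with the line of equal intensity and colours for families past an adjusted p of 0.05. The 62 families higher in vasa lie below the line and the 7 higher in uap56, copia and Tirant among them, lie above it.

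Several families did not pass the test. The telomeric HeT-A stood at 241 ± 28.5 in uap56 and 253 ± 154 in vasa, a log2 difference of 0.09 (adjusted p = 0.860) that was -0.29 without vasa replicate 1. TAHRE, the third telomeric element, had 0.90 (adjusted p = 0.0556). The values were 0.21 for roo (adjusted p = 0.410), 0.32 for Doc (adjusted p = 0.200), 0.29 for F-element (adjusted p = 0.294) and 0.35 for gypsy (adjusted p = 0.0943), whose weak signals gave 0.21 with a pseudocount of 16. P-element was not analysed here.

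**Figure D2:**
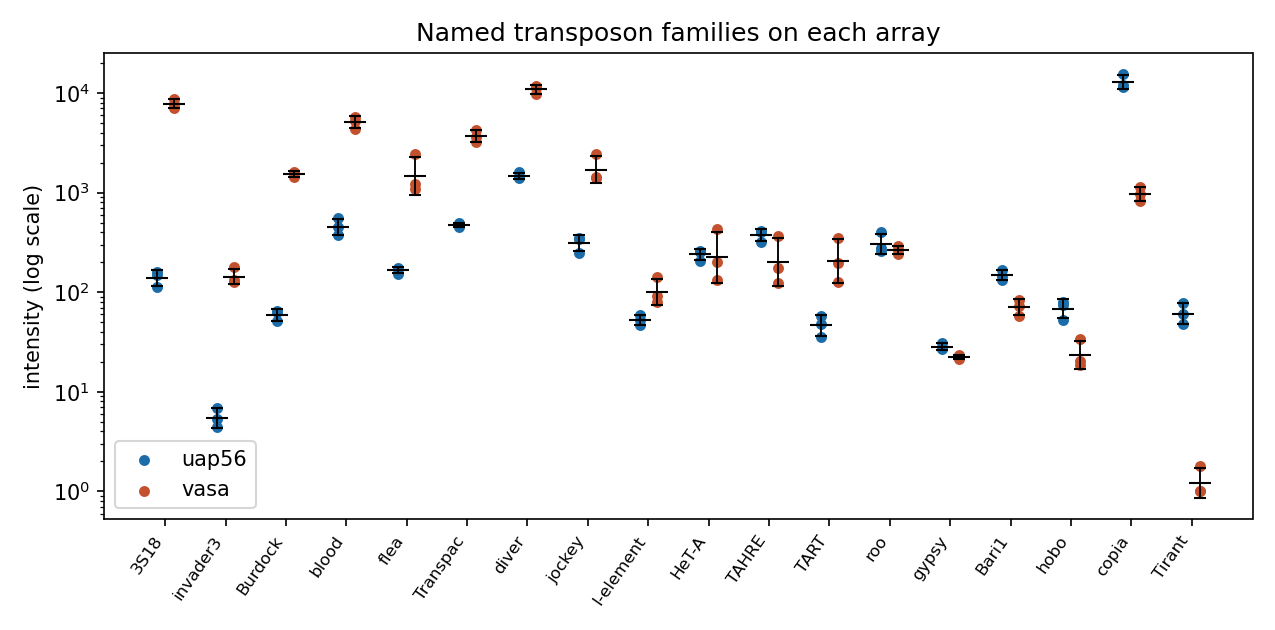
Intensity (log scale) of 18 transposon families on each array, uap56 in blue and vasa in red, where each point is an array, the black bar is the mean of the log2 values and the error bars are 1 SD on the log2 scale. The vasa arrays lie above the uap56 arrays for 3S18 to I-element, the groups overlap for HeT-A, TAHRE and roo, and the uap56 arrays lie above for copia and Tirant.

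By class, 42 of 59 LTR families were past the threshold toward vasa and 3 toward uap56, with a median log2 difference of -0.89. Of 35 LINE-like families, 18 were higher in vasa and 1 in uap56 (median -0.56). Of 22 DNA and foldback families, 1 was higher in vasa and 2, hobo and Bari1, in uap56 (median 0.01). Helitron, also past the threshold toward uap56, was in no class list and is not counted in these classes. Among 19 families listed as expressed in the germline, 13 were higher in vasa and copia alone in uap56 (median -1.75). Among 9 families of the somatic follicle cells, which the flamenco locus controls, 2 were higher in vasa and 0 in uap56 (median -0.19). Their signals were weak, with median intensities of 20.4 in uap56 and 22.3 in vasa, and this set was not tested with a pseudocount. Adjusted over the list alone, the counts toward vasa were 42 LTR, 16 LINE-like, 0 DNA, 13 germline-expressed and 2 follicle-cell families, and those toward uap56 were 3, 1, 2, 2 and 0. For the 3 telomeric elements the list alone gave TART toward vasa and TAHRE toward uap56. Against the other families, camera with a preset correlation placed the LTR class lower in uap56 (adjusted p = 0.00927) and the DNA class higher (adjusted p = 0.00106), and neither held with an estimated correlation (adjusted p = 0.654 for each). The other 4 sets were not past the threshold by camera (adjusted p = 0.432 to 0.991). For the LINE-like and follicle-cell sets the median was below 0 while camera gave an upward direction. Camera compares the mean statistic of a set with that of the other families. Fry, which asks whether the members of a set move one way on balance and not how they compare with others, gave an adjusted p of 0.00122 for LTR, 0.00839 for LINE-like, 0.00203 for germline-expressed and 0.0394 for follicle-cell families, all toward vasa, and 0.741 for DNA and 0.604 for telomeric families. The mean of the telomeric set was -0.39 and its median 0.09.

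Set against genes, the transposon families as a whole lay lower in uap56 than in vasa. Their median log2 difference was -0.55 and that of 13666 genes 0.02. Camera gave p = 5.48e-19 with a preset correlation of 0.01 and p = 0.0478 with an estimated correlation of 0.176, and fry, which does not compare the families with genes, gave p = 0.00138. With a pseudocount of 16 the median of the families was -0.35.

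The RefSeq tables show which genes differed between the same ovaries. The largest differences toward vasa included wwk, 30.9-fold higher in vasa (49.2 ± 3.90 in uap56 and 1528 ± 192 in vasa, n = 3 each), and esg, which encodes a zinc-finger transcription factor of the Snail family (8.10-fold, 45.2 ± 11.5 in uap56 and 375 ± 125 in vasa). Toward uap56, the relaxin-like peptide gene Ilp8 was 7.13-fold higher (2527 ± 286 in uap56 and 358 ± 73.4 in vasa) and Trf, which encodes a relative of the TATA-binding protein, 4.03-fold (463 ± 63.1 in uap56 and 116 ± 21.8 in vasa). The chitinase gene Cht2 was 4.37-fold higher in uap56 and the odorant-binding protein gene Obp99a 4.07-fold.

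In the planned limma fit with a single variance prior, 2 of 13666 genes passed: wwk (log2 difference -4.95, adjusted p = 0.00272) and CG15184 (adjusted p = 0.0233), which stood at 74.6 ± 30.0 in uap56 and at the floor on all vasa arrays and was named after its values were seen. The unadjusted p was under 0.05 for 2085 genes, and 3 passed with a variance per gene alone. With an intensity trend and robust hyperparameters, 522 genes passed, 340 higher in uap56 and 182 in vasa, of which 161 and 105 differed at least 2-fold. This trend fit names the genes from here on, a choice made after the planned count was known. The arrays of the groups did not overlap for 23.5% of genes, where chance gives 10%. The count was 68 without uap56 replicate 2, 200 without uap56 replicate 3, 87 without vasa replicate 2 and 89 without vasa replicate 3.

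The 12 largest differences toward uap56 in the trend fit were those of Ilp7 (2.99, adjusted p = 0.0198), Ilp8 (2.83, adjusted p = 3.61e-04), vas (2.52), the cytochrome P450 gene Cyp6a17 (2.14), Cht2 (2.13, adjusted p = 0.00579), the glutathione S-transferase gene GstT4 (2.08), Obp99a (2.03, adjusted p = 0.00777), Trf (2.01, adjusted p = 0.00556), CG3566 (2.01), CG15784 (4.01-fold), twit (1.95) and Srg3 (1.95). The 12 toward vasa were wwk, Pepck1 (-3.16, adjusted p = 0.0188), a gene of gluconeogenesis, esg (-3.02, adjusted p = 0.00556), dpr6 (-3.01, adjusted p = 0.00998), CG41559 (-2.91), CG11825 (-2.71), Oxp (-2.52), CG12896 (-2.50), CG11638 (-2.36), Drat (-2.31), CG41545 and the glutathione S-transferase gene GstE10. CG41545 (7.43 ± 7.29 in uap56 and 154 ± 80.0 in vasa, 1 uap56 array at the floor) and GstE10 (20.9 ± 17.99 in uap56 and 154 ± 35.6 in vasa) had weak signals in uap56, so their size and rank do not stand, with -2.80 and -2.28 after the pseudocount against -4.97 and -3.18 without it. Of these 24, wwk, esg, dpr6, CG12896, CG15784, Trf, Obp99a, Cht2, vas and Ilp8 passed in all 6 fits that left out 1 array. Ilp7 and Cyp6a17 passed in 2 of the 6 each, and their vasa signals were weak (52.5 ± 41.7 and 52.8 ± 28.6). With the pseudocount their differences were 2.56 and 1.77, and Ilp8, at 2.78, ranked above Ilp7. The number of the 24 that passed was 22 without uap56 replicate 1, 13 without uap56 replicate 2, 18 without uap56 replicate 3, 19 without vasa replicate 1, 13 without vasa replicate 2 and 14 without vasa replicate 3.

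**Figure D3:**
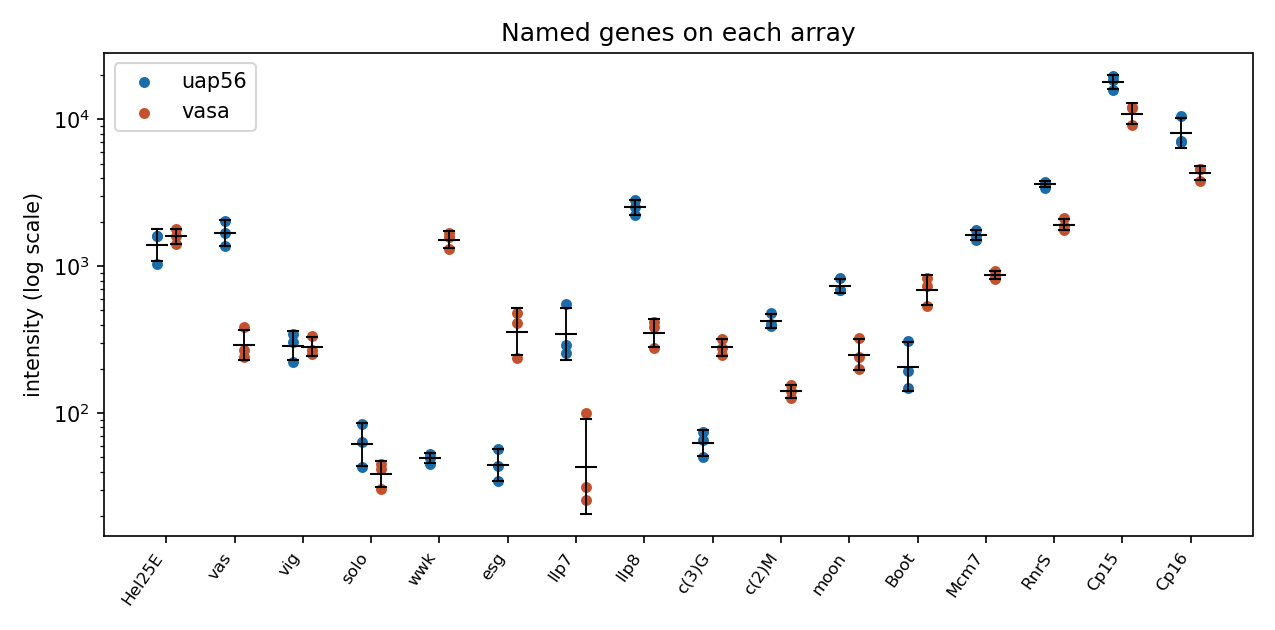
Intensity (log scale) of 16 named genes on each array, uap56 in blue and vasa in red, where each point is an array, the black bar is the mean of the log2 values and the error bars are 1 SD on the log2 scale. The groups overlap for Hel25E, vig and solo, the uap56 arrays lie above the vasa arrays for vas, Ilp7, Ilp8 and c(2)M, and the vasa arrays lie above for wwk, esg and c(3)G.

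Among 38 genes of the piRNA pathway, 4 were higher in vasa and 4 in uap56. Boot, whose product acts in export of piRNA precursors, was 3.32-fold higher in vasa (217.9 ± 84.5 in uap56 and 700.1 ± 152 in vasa), and piwi, which encodes the nuclear Argonaute of the pathway, 2.04-fold (409 ± 92.4 in uap56 and 824 ± 108 in vasa). The others toward vasa were BoYb (-1.75) and SoYb (-1.12). Toward uap56, moon, which encodes a transcription factor of piRNA clusters, was 2.95-fold higher (739 ± 84.4 in uap56 and 255 ± 63.9 in vasa), beside vas, Hen1 (0.88), whose product methylates piRNA ends, and squ (0.65). The values of aub, AGO3, rhi and cuff, which did not pass, were -0.48, -0.37, -0.27 and -1.01, and piwi, BoYb, SoYb, squ and these 4 were named after their values were seen. The median of the list was -0.31, and camera placed it lower in uap56 than other genes (adjusted p = 0.0172, adjusted p = 0.971 with an estimated correlation). Adjusted over the list alone, 7 members were higher in vasa and 5 in uap56. Of the members called over all genes, vas and moon passed in all 6 trend fits that left out 1 array. Boot passed in 3 of these fits, BoYb in 2, piwi and SoYb in 1 each, and Hen1 and squ in 0. Without uap56 replicate 3 the list's median was -0.19 (adjusted p = 0.147), and without vasa replicate 3 it was -0.30 (adjusted p = 0.0819).

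In the endocycle and DNA replication list, 4 of 26 genes were higher in uap56 and the others were not past the threshold. RnrS, the small subunit of ribonucleotide reductase, was 1.88-fold higher (3613 ± 170 in uap56 and 1929 ± 175 in vasa), and 3 subunits of the replicative helicase passed with it, Mcm7 (1.88-fold), Mcm5 (1.73-fold) and Mcm3 (1.70-fold). The median of 26 members was 0.47, with 21 above 0. Over all genes 4 members passed toward uap56 and 0 toward vasa, and adjusted over the list alone 13 and 0. Camera gave an adjusted p of 4.40e-04 (adjusted p = 0.971 with an estimated correlation) and fry 0.0711. Camera's call held in all 6 fits without 1 array, and with names joined regardless of letter case, which took in transcripts of another gene under Dp, the adjusted p was 0.00179.

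In the meiosis and recombination list, 6 of 31 members were higher in uap56 and 1 in vasa. Among them are genes of the synaptonemal complex. c(3)G, the transverse filament gene, was 4.47-fold higher in vasa (63.4 ± 12.4 in uap56 and 281 ± 36.9 in vasa), while c(2)M, of the lateral element, was 3.00-fold higher in uap56 (424 ± 48.6 in uap56 and 141 ± 14.1 in vasa). Toward uap56, spn-B was 3.15-fold higher (log2 difference 1.66, adjusted p = 0.0144) and the kinesin gene sub 1.89-fold. Also higher in uap56 were mtrm (0.70) and nanos (0.69), of which mtrm was named after its values were seen. The median was 0.17 and camera gave an adjusted p of 0.393. Adjusted over the list alone, the counts were 6 and 1.

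Among germ plasm and oocyte patterning genes (21 measured, median -0.21), nanos and vas were higher in uap56, and stau (-0.89, adjusted p = 0.0438) and Hrb27C (-0.62, adjusted p = 0.0244) in vasa. Among early germline genes (15 measured, median -0.17, mean 0.02), nanos and vas were higher in uap56, and ovo (-0.74, adjusted p = 0.0419) and mei-P26 (-1.05, adjusted p = 0.0475) in vasa. Camera placed neither list apart from other genes (adjusted p = 0.194 and 0.619). For the early germline it gave a downward direction, like the median, while the mean just above 0 includes vas at 2.52. Adjusted over the list alone, 2 germ plasm genes were higher in uap56 and 5 in vasa, and 2 and 2 early germline genes.

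Of the chorion genes of the eggshell, 2 were past the threshold. The genes Cp15 (18081 ± 1949 in uap56 and 11067 ± 1691 in vasa) and Cp16 (8241 ± 2013 in uap56 and 4311 ± 454 in vasa) were 1.64-fold and 1.88-fold higher in uap56, and 21 of 23 chorion genes had a difference above 0 (median 0.30). CG4066 (1.26, adjusted p = 0.0641) and Fcp3C (0.69, adjusted p = 0.151) did not pass. Camera placed the list higher in uap56 (adjusted p = 0.0116, adjusted p = 0.971 with an estimated correlation), and the median was 0.24 after quantile normalization (adjusted p = 0.0880), 0.14 without uap56 replicate 2 (adjusted p = 0.300) and 0.25 without vasa replicate 3 (adjusted p = 0.0819). Adjusted over the list alone, 3 chorion genes were higher in uap56. Of 17 vitelline membrane genes (median -0.01, adjusted p = 0.644), fs(1)N was higher in vasa (-0.68, adjusted p = 0.0477), the only call adjusted over the list alone too, while Vm26Ac had 0.70, clos -0.46 and yellow-g 0.55 without passing. The yolk protein genes were not past the threshold, with -0.20 for Yp1, -0.32 for Yp2 and 0.35 for Yp3, nor was the yolk receptor gene yl (-0.02), and the list of 4 had an adjusted p of 0.762. The follicle cell list held 25 measured genes, 19 of them below 0 (median -0.18). No follicle cell gene passed in the trend fit or when adjusted over the list alone, with kek1 at -0.99, stl at -0.72, Mmp2 at -0.62 and Egfr at -0.57. Camera placed the follicle cell list lower in uap56 (adjusted p = 0.0295, adjusted p = 0.971 with an estimated correlation), and its median was -0.22 without uap56 replicate 1 (adjusted p = 0.0868), -0.30 without uap56 replicate 2 (adjusted p = 0.0405), -0.19 without uap56 replicate 3 (adjusted p = 0.0985), -0.11 without vasa replicate 1 (adjusted p = 0.0850) and -0.22 without vasa replicate 3 (adjusted p = 0.0819).

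The lists of general cell functions were not past the threshold by camera. In the mRNA export and exon junction list, in which UAP56 itself acts, mago, a core gene of the exon junction complex, was higher in uap56 (0.95, adjusted p = 0.0361), while the THO complex genes thoc5 and thoc7 had 0.52 and -0.49 and Dbp80 0.56 without passing (median -0.00, mean 0.04, upward by camera with adjusted p = 0.939). In the spliceosome list U2af50 (0.89) and snRNP-U1-70K (0.82) were higher in uap56 and SmF (-1.29, adjusted p = 0.00921) in vasa (median 0.19, adjusted p = 0.231). Ribosomal protein genes had a median of 0.10 (adjusted p = 0.231), and RpS12 was higher in uap56 (0.70). Proteasome genes had 0.20 (adjusted p = 0.194), with Prosbeta5 (0.80) and Rpn12 (0.82) higher in uap56. Genes of oxidative phosphorylation had 0.22 (adjusted p = 0.121), with ND-30 (0.76) and SdhD (0.73) higher in uap56 and COX6B (-0.76) in vasa. The detoxification genes GstE1 (1.04) and Jheh2 (0.77) were higher in uap56 and GstE6 (-0.90) in vasa (median -0.14, adjusted p = 0.939). Of the DNA damage genes Irbp was higher in uap56 (0.65), and grp had 0.64 without passing (median 0.12, adjusted p = 0.619). Of the heat shock and chaperone genes Stip1 was higher in vasa (-0.60), and Hsp22 had 1.26 and Hsp26 0.40 without passing (median 0.25, adjusted p = 0.939). No gene of the antimicrobial peptide list passed (median -0.13, adjusted p = 0.575). TotA (21.1 ± 15.2 in uap56 and 69.2 ± 25.4 in vasa), Drs (49.2 ± 38.1 in uap56 and 8.51 ± 5.38 in vasa) and AttD had weak signals. The size of their differences does not stand, with -1.23, 1.26 and -0.60 with a pseudocount of 16 against -1.91, 2.51 and -1.22 without it. Def stood at the floor on all vasa arrays and on uap56 replicate 3. The remaining members with the smallest p in these lists did not pass, with 0.52 for U2af38, 0.68 for RpS16, 0.71 for RpL24, 1.12 for RpL38, -0.42 for Rpn5, 0.58 for Prosbeta1, 0.94 for levy, 0.71 for GstE5, 0.48 for mus304, 0.72 for Corp and 0.94 for CG4456. Adjusted over the list alone, the counts toward uap56 and vasa were 2 and 0 for mRNA export, 3 and 1 for the spliceosome, 7 and 0 for ribosomal proteins, 3 and 1 for each of the proteasome, oxidative phosphorylation and detoxification lists, 1 and 0 for DNA damage, 1 and 1 for heat shock and 0 for antimicrobial peptides.

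No list of other cell types that a dissected ovary can carry passed by camera. In the fat body list, Pepck1 and the lipase gene Lip4 (3.14-fold, 156 ± 18.8 in uap56 and 488 ± 39.7 in vasa) were higher in vasa and Obp99a in uap56 (median -0.14, adjusted p = 0.393), and adjusted over the list alone 3 and 1 members passed. No gene of the muscle, gut and Malpighian tubule, hemocyte, female reproductive tract, testis and male gland or neuron lists passed over all genes. The medians were 0.12 for muscle (adjusted p = 0.619), -0.21 for gut and tubule (adjusted p = 0.231), -0.11 for hemocytes (adjusted p = 0.575) and -0.31 for neurons (adjusted p = 0.0824). They were 0.07 for the reproductive tract (adjusted p = 0.939) and 0.02 for the testis and male gland (adjusted p = 0.939), both with a downward direction by camera, and the testis mean was -0.03. In the neuron list, 13 of 18 genes lay below 0 and fry gave an adjusted p of 0.0711. Syx1A stood at -0.90 (adjusted p = 0.0514) and Appl at -0.88 (adjusted p = 0.149), and adjusted over the list alone 1 member was higher in vasa. Members with the smallest p stood at -0.49 (brp) and -0.33 (Csp) for neurons, -1.04 (TpnC73F), 0.65 (Prm), 0.67 (Mf) and 0.72 (Mlp60A) for muscle, -1.32 (vkg), -0.59 (Pxn), 0.37 (ush) and 0.74 (PPO2) for hemocytes, and -0.80 (LManI), -1.01 (LManII), -1.17 (deltaTry) and -0.70 (epsilonTry) for the gut. They stood at -0.63 (Lgr3), -0.44 (lz) and 0.68 (fit) for the reproductive tract, and at -1.34 (SP), 0.62 (twe) and 1.08 (Acp36DE) for the testis and male gland. Send2 of the reproductive tract, ProtB of the testis and Npc2d of the fat body had weak signals in both groups, with 0.53, -1.25 and 1.17, or 0.28, -0.64 and 0.69 with a pseudocount of 16. Of the 25 lists, 4 passed by camera with a preset correlation, 0 with an estimated correlation and 0 by fry. In fry's mixed test, which asks whether members change in either direction, 14 passed. The mixed test does not compare a list with other genes, so its count does not set these lists apart. Over all genes 15.3% had an unadjusted p under 0.05 in the planned fit. Of the 44 list members past the threshold in the trend fit, vas, moon, c(2)M, c(3)G, SmF, Lip4 and Obp99a passed in all 6 fits that left out 1 array, and the number that passed was 32 without uap56 replicate 1, 7 without uap56 replicate 2, 14 without uap56 replicate 3, 29 without vasa replicate 1, 8 without vasa replicate 2 and 8 without vasa replicate 3.

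**Figure D4:**
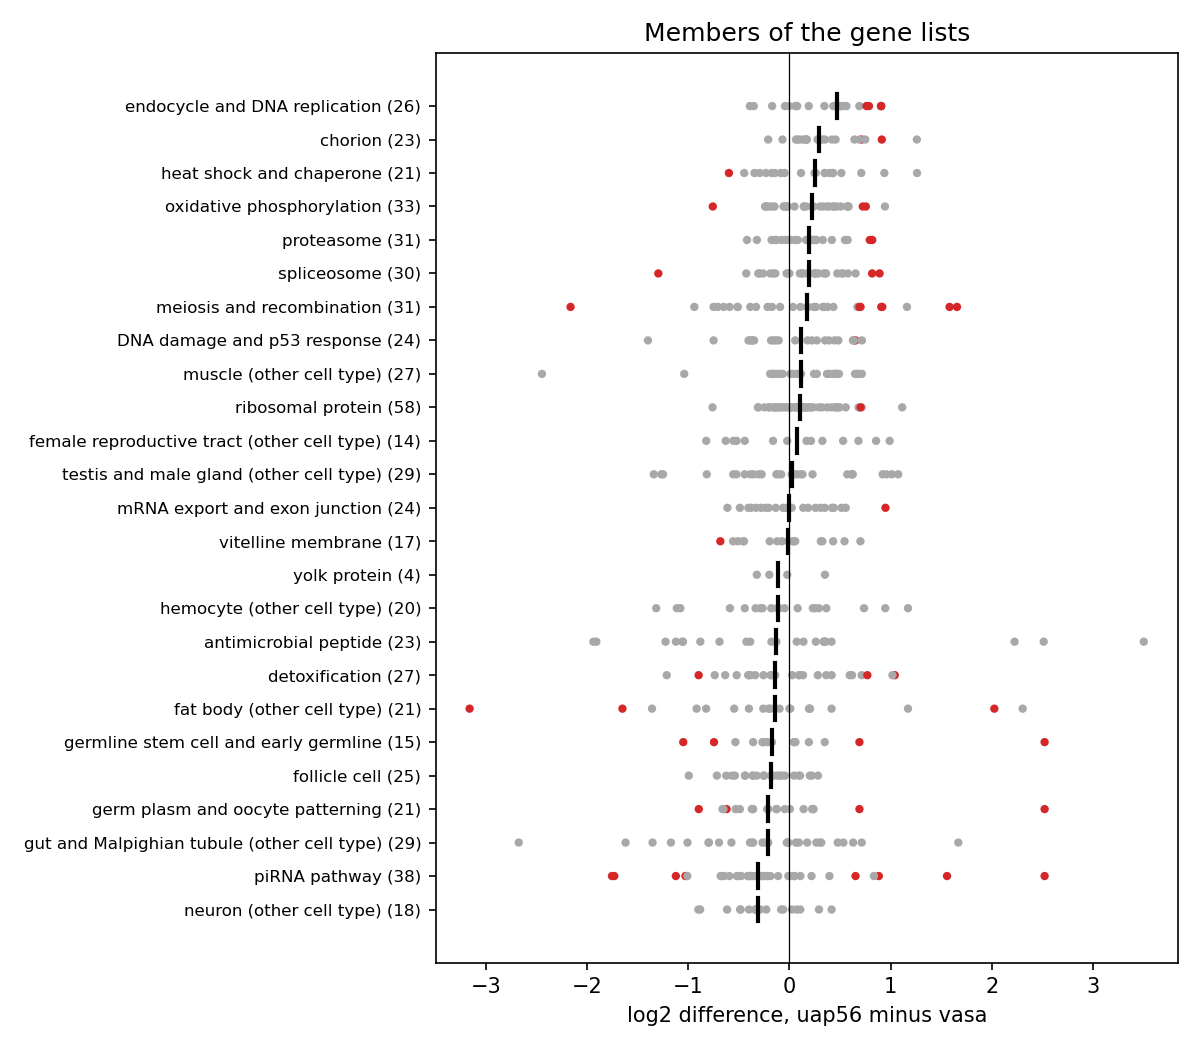
Log2 difference (uap56 minus vasa) of each measured member of the 25 gene lists, with the number of members in brackets, red points for genes with an adjusted p under 0.05 in the trend fit and a black bar at the median of each list. The endocycle and DNA replication median lies at 0.47 and that of the piRNA pathway at -0.31.

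Hel25E and vas both lie on chromosome arm 2L, and the arms of the genes past the threshold were compared for that reason. On 2L, 96 of 2417 genes passed in the trend fit (3.97%), against 3.89% on the other arms, an odds ratio of 1.02 (95% interval 0.807 to 1.29, Fisher's exact test, two-sided, adjusted p = 1.00). The share was lowest on 3R among the large arms (3.15%, adjusted p = 0.0745) and 4.80% on X (adjusted p = 0.0802). It was 4.52% on 2R (adjusted p = 0.154), 3.33% on 3L (adjusted p = 0.159) and 7.50% on chromosome 4 (adjusted p = 0.186). With older gene models kept apart from the current gene, 3R and X passed at an adjusted p of 0.0474 each. In the planned fit, wwk, on 2L, was the only gene past the threshold with a known arm (Fisher's exact test, p = 0.183).

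Near vas in the gene order, wwk lay 2 genes and esg 18 genes away, both higher in vasa, and mol (1.27) and CG15279 (1.75) higher in uap56, the last pair named after their values were seen. Among the 50 genes nearest vas, 4 passed in the trend fit, against 91 of 2366 on the rest of the arm (Fisher's exact test, p = 0.131). The 4 include wwk and esg, which prompted the comparison.

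**Figure D5:**
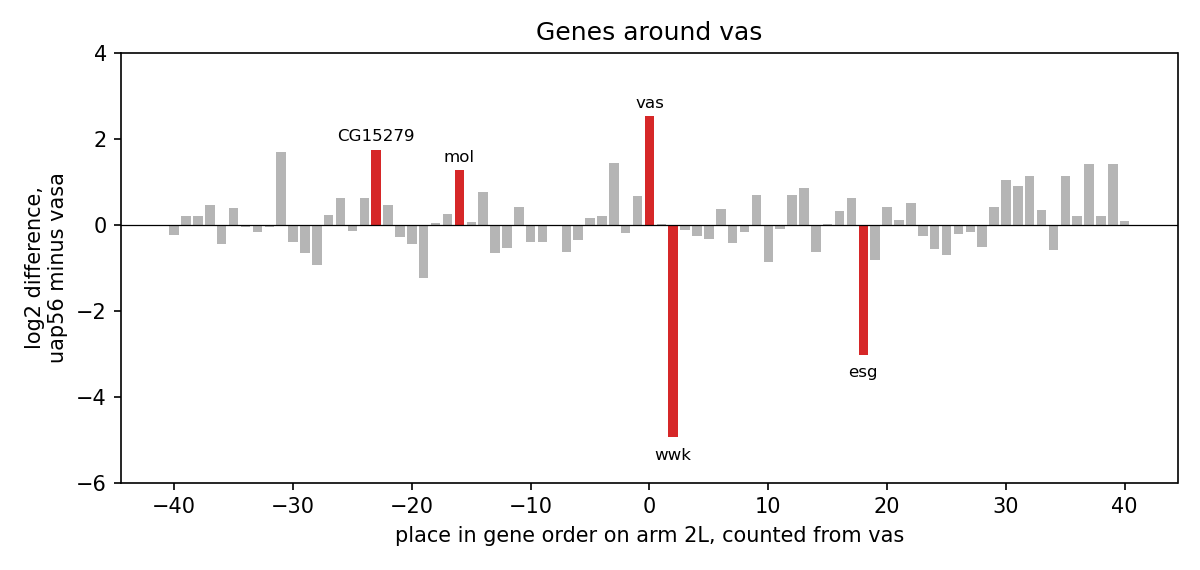
Log2 difference (uap56 minus vasa) of the genes around vas on arm 2L by their place in the gene order, counted from vas, with red bars for genes with an adjusted p under 0.05 in the trend fit. Bars above 0 are higher in uap56, among them vas (2.52), and bars below 0 higher in vasa, among them wwk (-4.95) and esg (-3.02).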

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

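The pseudocount of 16, the older gene models kept apart, names joined regardless of letter case and the trend fit for vas, Hel25E, the arms and list members were chosen after seeing the data. The number of transposon families past the threshold was 54 to 68 in all alternatives but 1, the fit in 1 table with the genes, with 13 families (2 and 11 toward uap56 and vasa). That fit changes both the variance prior and the number of entries adjusted over, and the cause was not tested. The median difference of the families was -0.61 to -0.50 without 1 array and -0.35 with the pseudocount, against -0.55. The largest p of the shift, 0.0478, came from camera with an estimated correlation on all arrays as deposited. That test was not repeated without an array, with the block, after other scaling, above the 25th percentile or with the pseudocount. In those alternatives camera had the preset correlation of 0.01. The planned count of 2 genes was 0 with the replicate number as a block, 143 above the 25th percentile, 522 with the intensity trend and robust hyperparameters, 53 with the pseudocount, 1 at a threshold of 0.01 and 0 to 8 without 1 array. With the trend and robust options apart, 276 genes toward uap56 and 136 toward vasa passed with the trend alone and 2 with robust hyperparameters alone, fits added after seeing the data; for the block, the percentile and the pseudocount the cause was not tested. The trend count was 271 with the block, 726 after quantile normalization and 705 after centring. The number of gene lists past the threshold was 0 with an estimated correlation, 0 by fry and 1 to 8 without 1 array, and the follicle cell list was lost with the block (adjusted p = 0.0562). For vas, the log2 difference was 2.52 with an adjusted p of 0.0223 above the 25th percentile, 2.52 with 0.00174 in the trend fit and 2.46 with 0.0384 with the pseudocount, each past the threshold that the planned fit missed; the cause was not tested. Signs changed for Hel25E (leave-one-out range -0.31 to 0.00399), vig (-0.0205 after quantile normalization, -0.12 to 0.21 without 1 array), yl (-0.0888 to 0.0362 without 1 array) and HeT-A (-0.29 to 0.56 without 1 array), none of which passed the test in any fit; the cause was not tested. Joined regardless of letter case, the names left the endocycle and DNA replication list at an adjusted p of 0.00179 against 4.40e-04, and with older gene models kept apart arms 3R and X passed at 0.0474 each against 0.0745 and 0.0802. The median of all genes was 0.02 as deposited, 0.02 after quantile normalization and 0.02 after centring. The arms gave no value with the block, without uap56 replicate 2, without vasa replicate 2 and without vasa replicate 3, since no gene with a known arm passed. The spread of dim genes limits what can be seen, with a median residual SD of 0.81 on the log2 scale in the dimmest 25% of genes and 0.21 in the brightest.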

Other observations

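Every test of an explanation in this part was chosen after its pattern had been seen; what the outcome would mean was set before the test's own value was known for weak signals and other splits of the arrays, and after related values were known for germline cells, transposon copies, the genes around vas, noise and intensity, heterochromatic gene models and glycolysis.

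Of 14 glycolytic genes, 12 had a difference above 0 and 5 passed toward uap56. The list was drawn up after the values were seen, so the p-values of its set tests are not independent of this pattern. In the trend fit Pgk (1.16, adjusted p = 0.0172), Tpi (0.94, adjusted p = 0.0325), Eno (0.91, adjusted p = 0.0139), PyK (0.82, adjusted p = 0.0139) and Gpdh1 (0.58, adjusted p = 0.0350) were higher in uap56, with Eno, which encodes enolase, at 4194 ± 429.8 in uap56 and 2239.9 ± 297.2 in vasa. The values of Gapdh1, Pgi and Pfk were 0.60, 0.57 and 0.56 without passing, and Hex-A (-0.07) and Ldh (-0.35) lay below 0. As a hypothesis, glycolysis may differ as a set: the median of 14 genes was 0.56, with 12 above 0, and camera gave p = 4.59e-06 with a preset correlation and p = 0.107 with an estimated correlation, and fry p = 0.00393, so the set test was not past the threshold in every form and the question stays open. Of the 5 genes past the threshold, 3 passed without uap56 replicate 1, 0 without uap56 replicate 2, 2 without uap56 replicate 3, 4 without vasa replicate 1, 0 without vasa replicate 2 and 1 without vasa replicate 3.

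Gene models with names of the form CG40xxx or CG41xxx, or CR in place of CG, where each x is a digit, mostly belong to heterochromatin. Among them were CG41545 and CG41559, both past the threshold toward vasa in the trend fit. As a hypothesis, such models may be over-represented among genes higher in vasa: 10 of 407 models passed toward vasa against 172 of 13259 other genes, an odds ratio of 1.92 (95% interval 0.896 to 3.65, Fisher's exact p = 0.0721), which leaves the question open. Toward uap56, 1 of these models passed.

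Most transposon families that differed were higher in vasa, while copia and Tirant were higher in uap56. Genes of like intensity showed no such shift: 0 of 10000 gene lists matched in intensity reached the transposon median of -0.55. The medians of these lists ran from -0.23 to 0.27. Genes were drawn independently, while the families had an estimated correlation of 0.176, so this range is too narrow for the families. With a pseudocount of 16 the median of the families was -0.35, so a part for weak signals stays open. The median of 32 germline genes other than vas was -0.21, against -1.75 for the germline-expressed families. These 2 values argue against a different share of germline cells as the whole cause. The 95% interval of -0.36 to -0.02 resampled genes and not arrays. It is too narrow, since the germ plasm and early germline lists had estimated correlations of 0.383 and 0.445. Different transposon copies in the stocks remain open: 1 family, Tirant, stood at an intensity of 2 or less on all arrays of 1 group only, and a family that differs in copy number need not reach the bottom of the scale. The difference between the uap56 and vasa groups themselves could account for the pattern as well and was not tested, since each group comes with its own flies. Of the 10 splits of the 6 arrays, 1, the real one, gave at least 69 families, and the highest of the others gave 0; 10 splits are too few for a share under 0.05.

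Near vas in the gene order, wwk and esg were higher in vasa while vas itself was higher in uap56. A block of linked alleles around vas is a candidate explanation: among the 50 genes nearest vas 4 passed in the trend fit, against 91 of 2366 on the rest of arm 2L, an odds ratio of 2.17 (95% interval 0.556 to 6.14, Fisher's exact p = 0.131). The 4 were wwk, esg, CG15279 (1.75) and mol (1.27), and near Hel25E 1 of 50 passed. Since wwk and esg prompted the comparison and are counted among the 4, the odds ratio is no separate support for a block. The counts are too few to decide, and a difference that follows from the groups themselves stays open, untested.

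The planned fit gave 2 genes and the trend fit 522. Noise that depends on intensity may account for this: the median residual SD fell from 0.81 in the dimmest 25% of genes to 0.21 in the brightest, a ratio of 3.93. With the intensity trend alone 276 genes passed toward uap56 and 136 toward vasa, and with robust hyperparameters alone 2 genes in all, so the trend brings most of the rise and the robust option adds to it only beside the trend. Other splits of the arrays leave the size of the count open: at least 2 genes passed in 4 of 10 splits in the planned fit (highest other 3), and at least 522 in 1 of 10 in the trend fit (highest other 1), and 10 splits are too few for a share under 0.05. The trend count was 68 without uap56 replicate 2, 200 without uap56 replicate 3, 87 without vasa replicate 2 and 89 without vasa replicate 3. No biological explanation was tested for this pattern.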
